A study of Gallus gallus with 10 samples.

How the data were processed

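Single-cell RNA of Müllerian ducts, the paired embryonic tubes that form the oviduct in female birds and regress in males, was measured in wild-type chicken embryos with the 10x Genomics Chromium 3′ chemistry and CellPlex tags, which are lipid-anchored oligonucleotides that mark the cells of each tube. The series has 10 samples: 5 gene expression libraries and 5 tag libraries made from the same cells. Each gene expression library is 1 10x channel and 1 group: embryonic day (E) 6.5 with male and female embryos mixed, E8.5 female, E8.5 male, E11.0 female left duct and E11.0 female right duct. The labels describe 3 tag-marked technical replicates in each channel, and the right-duct channel holds 1 further tag-marked portion of duct tips. The treatment field of the E6.5 sample names its replicates by another day than its title does. The day of the title is used here.

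The deposited matrices hold UMI counts per gene and cell, which the authors made with Cell Ranger 8.0.1 against the genome build GRCg7b, per the submitters' processing notes. Seurat and Scanpy are named in those notes too, and their versions and settings are not given in the sources used here. The 16 matrices hold 48528 barcodes, 16711 genes and 249016480 UMIs, each with the counts of 12 tags beside the genes. Every matrix belongs to 1 tag, and its own tag made up at least 95.19% of the tag counts in each. The lowest number of UMIs per barcode was 500. Gene positions were taken from the reference annotation of the same build, and 3435 genes without a symbol were used in clustering but not named.

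Cells with fewer than 500 detected genes or over 15% of UMIs from the 13 mitochondrial genes were removed, which left 43647 cells. The share of barcodes kept was 63.2% at E6.5, where 2048 barcodes were over the mitochondrial limit, and between 92.6% and 94.4% in the other groups. Doublet scores were computed per channel with Scrublet, as carried by Scanpy 1.11.5, at an expected share of 5%. It called 9 cells at E6.5, 100 in the E8.5 male, 1 in the right-duct channel and 0 in the E8.5 female and left-duct channels, all far below the expected share, and its calls were not used to remove cells. Doublets therefore remain in the data.

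Counts were scaled to 10000 per cell and log-transformed. The 2000 most variable genes over all cells, 30 principal components and a shared-neighbour graph of 15 nearest neighbours were used for Leiden clustering with leidenalg 0.10.2 at a resolution of 0.5. No correction between channels was applied. Each of the 23 clusters was given the class with the highest mean score over 13 marker lists fixed before the data were examined, on condition that at least 3 markers were found in at least 20% of its cells. Class names end in "-like" because they rest on those markers alone. A pair of clusters was left unnamed by thresholds chosen after the clusters were seen: 740 cells led by genes of perivascular cells, and 258 cells with a median mitochondrial share under 1%. These unnamed cells made up between 1.53% and 3.66% of each group.

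Each group is 1 channel of pooled embryos, so there is 1 sample per group and no test between groups was made. The technical replicates are tag-marked portions of 1 channel. The labels do not say whether these come from 1 pool of embryos, and at E6.5 they differ in the share of cells with RNA of 4 W genes (70.47%, 21.75% and 22.73%), so ranges over them can hold differences between embryos. No p-value, standard error or count of changed genes over the genome was computed from them. Within each class, UMIs were summed per group and per technical replicate and expressed as CPM, the usual unit of counts scaled by the total, here the class total. A log2 ratio of CPM is given with a 95% exact interval (Clopper-Pearson), which covers counting error only and not differences between embryos, dissections or channels. A gene is called higher or lower when its group sums differ at least 2-fold, every technical replicate of 1 group lies above every one of the other, and the higher group has at least 20 counts. Random order puts 10% of genes at such a separation for 3 against 3 technical replicates, and 50% outside the range of 3 for the single tip portion. A gene with 0 counts was set to a floor of 3 counts over the group, and its ratio is then a bound. The median log2 ratio over all measured genes lay between -0.07 and 0.06 in the epithelium and mesenchyme of the 6 comparisons, so no shift of all genes was subtracted.

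Fixed before the data were examined were 17 gene lists with 452 genes and the rule for named genes. In the duct epithelium-like and mesenchyme-like classes the rule takes the 5 highest and 5 lowest ratios among called genes with a symbol and at least 50 CPM in the higher group. It leaves out haemoglobin genes, and sex-linked genes where the sexes are compared. It adds the largest called members of each list, and AMHR2, WNT4, WNT7A, PAX2, PAX8, LHX1, EMX2, DMRT1, ESR1, PGR, MMP2 and SP7 whatever their values. A further gene of this rule is not reported here. PAX8 and SP7 are not among the symbols of the matrices. The median log2 ratio of a list is given with its percentile among 10000 random lists of the same size and like expression, drawn over 20 expression bins. That percentile describes these libraries and is not a test between groups. Percentiles of 0.00 and 100 mean that no random list, or every random list, lay below.

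Free RNA in droplets adds transcripts of abundant cells to all others. Each named gene was therefore set beside its level in erythroid-like cells of the same group, which should lack the genes of duct and stroma. Of 132 named values in duct epithelium-like cells, 20 were at or below that level in the higher group, and of 187 in mesenchyme-like cells, 5 were. This check was chosen after the values were seen. Erythroid-like cells can hold more stromal RNA than the epithelium does, for a reason that was not tested. In the E11.0 left duct COL1A2 was at 882.7 CPM in erythroid-like and 203.1 CPM in duct epithelium-like cells. A gene at or below the erythroid-like level may thus be free RNA but is not shown to be.

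Depth per channel portion ran from 13876985 UMIs in the duct tips to 53680544 in the E8.5 male, and per technical replicate from 9537576 to 20866878. Shares of cells with a UMI were also computed after thinning every cell to 2000 UMIs. The rule for called genes was tested on simulated data, with 200 genes drawn in each of 20 simulations, part of them altered and the rest unaltered. In mesenchyme-like sums it recovered 48.3% of 2-fold, 98.2% of 3-fold and 99.2% of 4-fold differences, and with 1 portion against 3 in duct epithelium-like sums it recovered 47.6%, 91.2% and 95.7%. Between 0.0% and 2.65% of unaltered genes were called. The simulated data held counting error and a spread between technical replicates (SD from 0.072 to 0.122 in log2). They held no differences between embryos, dissections or channels, so these shares are not rates of false calls between the groups.

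The alternatives tried were other cell filters, Leiden resolutions of 0.3 and 1.0, clustering each channel alone, doublet removal, other size factors, totals without haemoglobin, mitochondrial and ribosomal protein genes, means over technical replicates, other minimum counts, thinning of the deeper group, and leaving out each technical replicate. NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, python-igraph 0.11.9, matplotlib 3.10.9 and Python 3.11.15 were used. The matrices are already split by tag, and the tag counts were used only to check that assignment.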

Results

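Single-cell transcriptomes of chicken Müllerian ducts were measured at embryonic days 6.5, 8.5 and 11.0. The 5 groups are mixed-sex ducts at E6.5, female and male ducts at E8.5, and left and right female ducts at E11.0, with 1 10x channel of pooled ducts each and 3 tag-marked technical replicates per channel. The right-duct channel also holds 1 tag-marked portion of duct tips. After filtering, 3543 cells remained at E6.5, 10556 in the E8.5 female, 8035 in the E8.5 male, 13140 in the left duct, 5834 in the right whole duct and 2539 in the right tip. Their median UMIs per cell were 10238, 3701, 6025, 3425, 5158.5 and 4925. There are no replicate samples of a group, so every value below describes these libraries. Error bounds are 95% exact counting intervals, and ranges are over technical replicates.

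The E6.5 library held a mixture of duct-like, kidney-like and coelom-like cells, and the later libraries were mostly stroma-like. Shares depend on dissection and on cell recovery, so they describe the libraries and need not hold for the ducts. Mesenchyme-like cells were 40.9% of cells at E6.5, 67.03% in the E8.5 female, 73.12% in the E8.5 male, 46.82% in the E11.0 left duct and 48.42% in the right whole duct. Smooth muscle-like cells were 0.31% at E6.5, 7.45% in the E8.5 female and 0.70% in the E8.5 male. At E11.0 they were 30.77% on the left, 32.33% on the right and 39.74% in the right tip. The name covers unlike cells. In them ACTG2 was at 326.9 CPM in the right whole duct, 70.42 CPM in the tip and 12.82 CPM in the E8.5 female. ACTA2 in the E8.5 female ones, 125.1 CPM, was above its mesenchyme-like cells (49.24 CPM) but near E6.5 mesenchyme-like cells (121.3 CPM). The larger share of the tip thus does not show more smooth muscle. Duct epithelium-like cells were 5.81% at E6.5, 12.14% in the E8.5 female, 7.70% in the E8.5 male and 7.86% and 5.71% in the left and right ducts at E11.0. Mesothelium-like cells, which line the coelom, were 21.82% at E6.5 and between 7.95% and 10.52% in the later groups. Wolffian or nephric duct-like cells were 19.28% at E6.5 and at most 0.66% in any later group. Erythroid-like cells were between 0.53% and 3.78%, and within the E8.5 male they ran from 0.89% to 8.26% over its technical replicates. The border between mesenchyme-like and smooth muscle-like cells rests on the clustering, and so does the order of the E6.5 and E8.5 shares. At a Leiden resolution of 0.3, 4.72% of E8.5 female cells were mesenchyme-like, and smooth muscle-like cells were 11.32% at E6.5, 69.82% in the E8.5 female and 3.12% in the E8.5 male. With each channel clustered alone, 17.3% of E6.5 cells and no cells of either E8.5 group were smooth muscle-like.

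**Figure D1:**
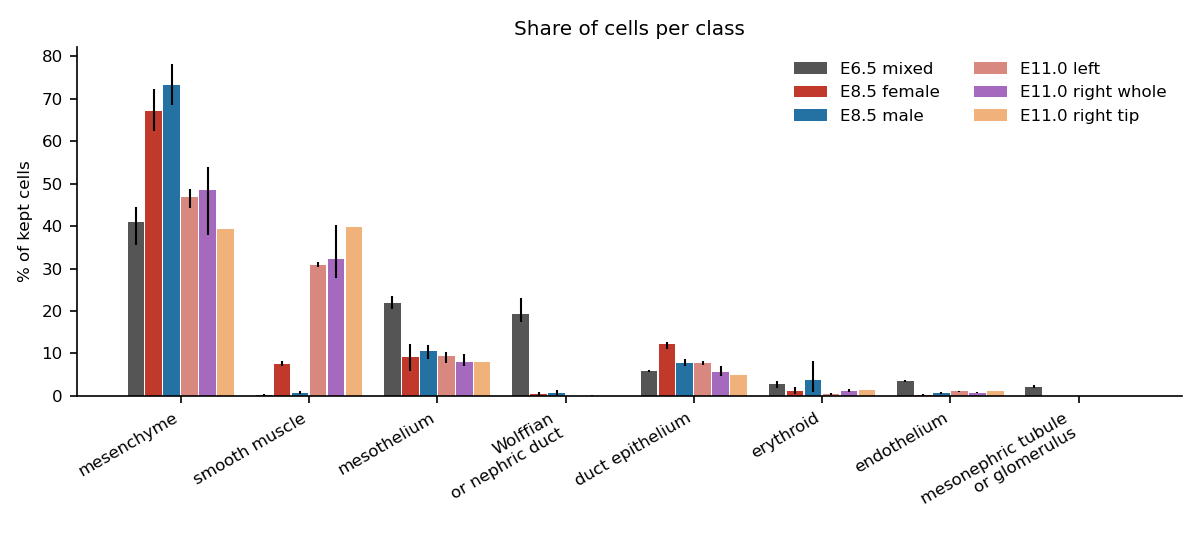
Share of kept cells in 8 classes (y axis, percent) for each group, with the right E11.0 duct split into whole duct and tip; bars are group values and lines run from the lowest to the highest technical replicate. Smooth muscle-like cells stand at 7.45% in the E8.5 female, 0.70% in the E8.5 male and 30.77% in the E11.0 left duct.

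RNA from the W chromosome, which female birds alone carry, was used to check the sex labels. HINTW, a W gene (ENSGALG00010011988, chromosome W, 2901766 to 2911002), stood at 301.2 CPM in the E8.5 female and 0.0381 CPM in the E8.5 male, from 14208 and 2 counts. Cells with a UMI of any of 6 W genes were 75.09% of the E8.5 female (interval 74.25 to 75.91) and 26.66% of the E8.5 male (25.69 to 27.64). The male share came almost wholly from NEDD4L, which the reference places on W but which stood at 59.28 CPM in the male and 32.12 CPM in the female, from 3115 and 1515 counts. The shares for 6 genes thus count RNA that male cells also hold, and do not measure W RNA alone. With HINTW alone the shares were 59.85% and 0.02%. The left duct, right whole duct and right tip at E11.0 had 57.47%, 72.25% and 67.39% of cells with HINTW. The E6.5 group had 36.92% of such cells, with 63.95% in technical replicate 1, 19.87% in replicate 2 and 20.41% in replicate 3. After thinning to 2000 UMIs, the shares for the 6 genes were 56.93% in the E8.5 female and 10.26% in the E8.5 male, with 1450 and 89 cells too shallow to thin.

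**Figure D2:**
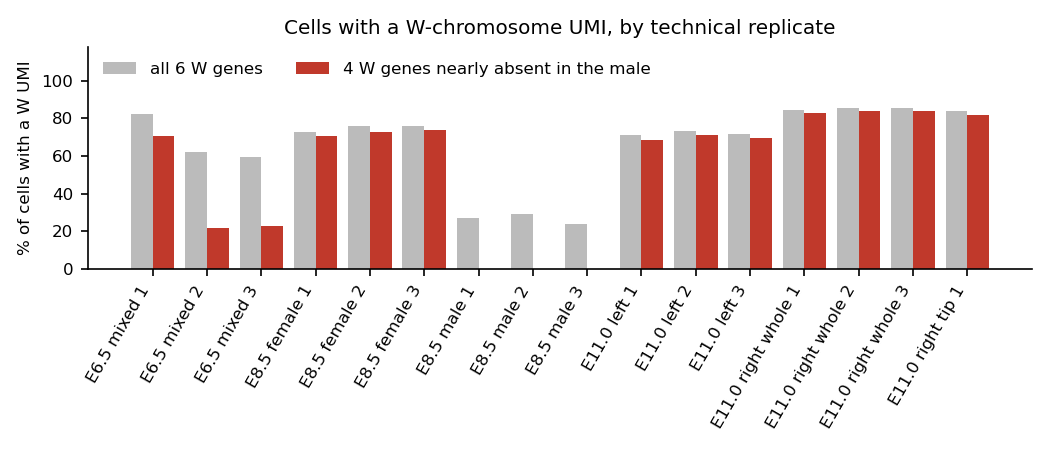
Share of cells with at least 1 UMI of W-chromosome genes (y axis, percent) in each technical replicate, for all 6 W genes and for the 4 that male cells nearly lack, a set chosen after the values were seen. In E6.5 replicate 1, 70.47% of cells held RNA of the 4 genes, against 21.75% and 22.73% in replicates 2 and 3.

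Female ducts at E8.5 were compared with mixed-sex ducts at E6.5, the earlier stage of the series. In mesenchyme-like cells OSR2, an odd-skipped transcription factor (ENSGALG00010011297, chromosome 2, 127399712 to 127404521), had the largest ratio among genes with at least 50 CPM, with 520.3 CPM against 33.25 CPM, a log2 ratio of 3.97 (3.84 to 4.10). CPLX1 (3.58), SEMA3C, a secreted guidance factor (3.28), and PCSK1, a prohormone convertase (3.22), were next, and GLRX (3.80) was at or below its level in erythroid-like cells. Lower in the E8.5 female were ANXA1 (-4.59), EBF3 (-4.01), COL8A1, a short-chain collagen (-3.83), and EBF1 (-3.80). AvBD10, a beta-defensin, was lower by the largest ratio (-6.49), and it stood at 27560 CPM in Wolffian duct-like cells of E6.5. In duct epithelium-like cells MSX2, a homeobox factor downstream of BMP signals (ENSGALG00010008416, chromosome 13, 9409592 to 9415374), was at 86.97 CPM against 1.635 CPM, a log2 ratio of 5.73 (4.60 to 7.18). DLX5, another homeobox factor (3.35), GRIN2A (2.41) and CACNB2 (1.84) were higher too. HTR2C, a serotonin receptor (-2.42), SEMA3D (-1.99), AvBD10 (-1.97), RBFOX1, a splicing factor (-1.89), and LSAMP (-1.81) were lower. LVRN (4.48) was below its level in erythroid-like cells.

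Of the genes on the fixed lists, 33 of 368 measured in mesenchyme-like cells were higher in the E8.5 female and 57 were lower, and 17 and 15 of 337 in duct epithelium-like cells, where 8 of the 17 were at or below their levels in erythroid-like cells. The epithelial counts were 10 higher and 24 lower with the highest 5% of Scrublet scores removed, an alternative chosen after the data were seen. HOX genes, which pattern the body axis, were 7 higher and 0 lower of 31 in mesenchyme, with a median log2 ratio of 0.37 (percentile 100) and HOXD11 at 2.46, HOXD12 at 2.15 and HOXD13 at 1.85. Hedgehog, FGF and Notch genes included 11 lower members of 27, among them DLL1 (-3.43), FGFR3 (-3.12) and HHIP (-2.98), and 2 higher. Extracellular matrix genes were 8 lower and 2 higher of 38, with a median of -0.28 (percentile 0.02), led by MMP11 (-2.88), TNC (-2.81) and LAMA1 (-2.40). Duct formation factors were 8 lower and 2 higher of 20, with TBX18 at -4.32 (-7.46 to -2.28, from 2 counts), GATA3 at -3.00 and SALL1 at 2.84. The GATA3 level in E6.5 mesenchyme, 2.384 CPM, was below that in erythroid-like cells. In the AMH and BMP list ID1 (2.04), ID4 (1.70) and BMP7 (1.69) were higher, and 4 of 23 were lower. WNT genes held WNT11 at -3.41, WNT5B at 1.43 and WNT6 at 1.41. In the retinoic acid list CRABP1 (-3.90) and ALDH1A1 (-2.51) were lower and ALDH1A3 (1.41) was higher. Smooth muscle genes were 4 higher and 3 lower of 17, with MYOCD, the coactivator of smooth muscle genes, at 1.56. In the epithelium the AMH and BMP list had 5 of 24 higher, 1 of them at or below its erythroid-like level, and 1 lower, with a median of 0.33 (percentile 100), and among these SMAD9 was at 1.72 and MSX1 at least 17.7-fold higher, from 131 and 0 counts. All 3 higher matrix genes and both higher HOX genes of the epithelium, HOXA9 and HOXA10, were at or below their levels in erythroid-like cells.

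Of the genes named in advance, ESR1, the estrogen receptor (1.43), and EMX2, a homeobox gene needed for duct formation (1.03), were higher in E8.5 female mesenchyme, and PAX2 (-1.26) was lower. The others reported here lay between -0.58 (PGR) and 0.81 (LHX1). None was called in the epithelium, where they lay between -0.86 (MMP2) and 1.51 (PGR). Dissociation stress genes had 5 lower of 25 in mesenchyme (median -0.23) and 3 lower of 22 in epithelium (median -0.25). Without E6.5 replicate 1, which has the most W RNA, the counts were 31 higher and 54 lower in mesenchyme and 20 and 10 in epithelium. Most E6.5 mesenchyme-like cells were in clusters 6 (43.82%) and 14 (28.57%) and most E8.5 female ones in cluster 1 (71.58%), and stage, sex makeup and channel cannot be told apart. Genes on the Z chromosome had a median log2 ratio of -0.55 in mesenchyme and -0.42 in epithelium, beside -0.05 and -0.02 for autosomal genes. Of the genes named for this comparison, ANXA1, GLRX, CPLX1, PCSK1 and LVRN lie on Z. At a Leiden resolution of 0.3, the counts in mesenchyme were 12 higher and 29 lower. At that resolution HOXD11 was at -0.46, EMX2 at -0.36, TBX18 at 0.48, WNT6 at -0.27 and the matrix median at 0.14. With each channel clustered alone the lower count in the epithelium was 47.

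**Figure D3:**
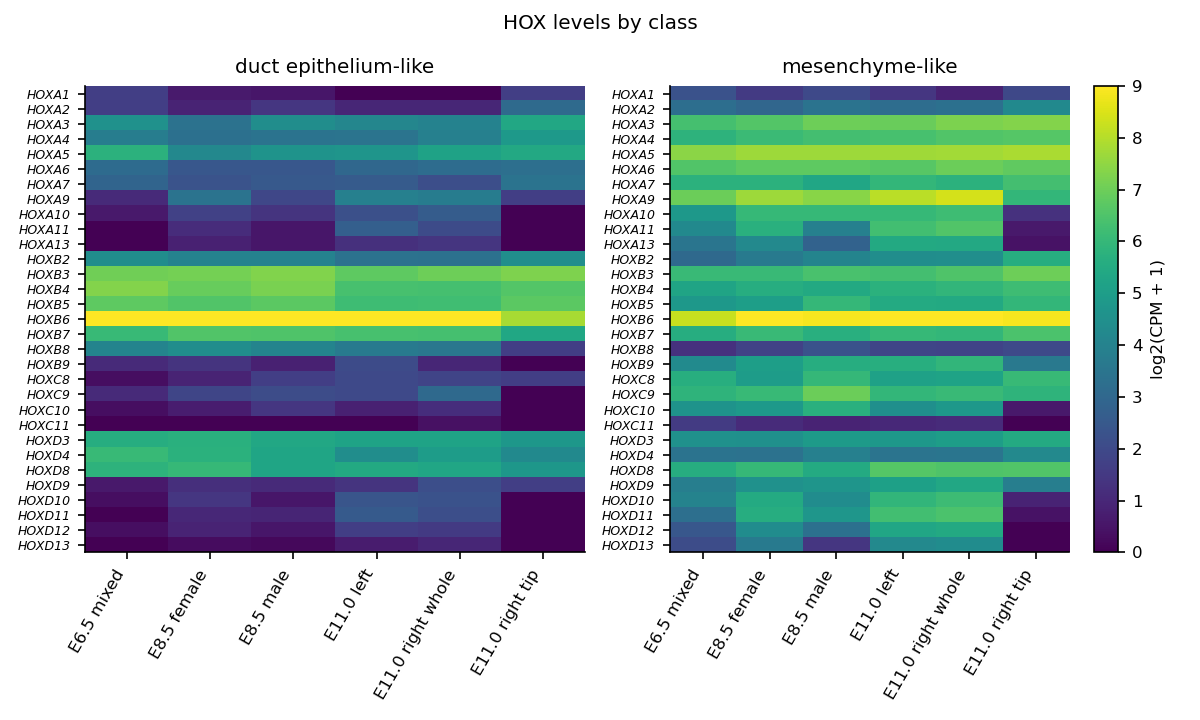
Levels of 31 HOX genes, as log2 of CPM plus 1 (colour), in duct epithelium-like and mesenchyme-like cells of each group (columns). HOXD11 in mesenchyme-like cells is at 85.8 CPM in the E11.0 right whole duct and 0.353 CPM in the right tip.

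Male ducts at E8.5 were compared with the same mixed-sex E6.5 group. In mesenchyme-like cells MSX1, a homeobox factor of the BMP pathway (ENSGALG00010011141, chromosome 4, 78333015 to 78335519), was at 243.2 CPM against 0.795 CPM, a log2 ratio of 8.26 (7.45 to 9.21). TBX20, a T-box factor (7.59), PENK, the enkephalin precursor (6.55), CLEC14A (5.59) and RAPGEF4 (5.38) were next among called genes with at least 50 CPM. AMHR2, the receptor of anti-Müllerian hormone, was at 2.349 CPM in male mesenchyme from 85 counts and 0.133 CPM at E6.5 from 2 counts, a log2 ratio of 4.15 (2.25 to 7.22). LIX1 (-3.31), CDH4 (-2.92) and KERA, a matrix proteoglycan (-2.88), were lower, as was AvBD10 (-3.16). In the epithelium RORB, a nuclear receptor (ENSGALG00010015250, chromosome Z, 37158099 to 37295153), was at 196.2 CPM against 5.177 CPM, a log2 ratio of 5.24 (4.59 to 5.98). TAGLN (4.70) and ACTG2 (3.36), proteins of the smooth muscle cytoskeleton, TC2N (3.88) and SORCS1 (3.37) were higher too. KIT, a receptor tyrosine kinase (-3.66), PRRX1 (-2.88), HGF (-2.81) and NPM3 (-2.21) were lower. HINTW had 0 counts in male cells of both classes, at least 1365-fold lower in mesenchyme and at least 367-fold lower in epithelium.

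Male mesenchyme differed from E6.5 in 49 higher and 85 lower of 375 list genes, and male epithelium in 35 higher and 22 lower of 333. Cell cycle genes made up a large part of the lower set in mesenchyme: 27 of 31 were lower and 0 higher, with a median of -1.21 (percentile 0.00) and RRM2, a subunit of ribonucleotide reductase, at -2.09, CDC6 at -1.74 and GINS2 at -1.73. In the epithelium 3 of 31 were lower and the median was -0.71 (percentile 0.00). AMH and BMP genes were 11 higher and 5 lower of 27 in mesenchyme, with a median of 0.71 (percentile 100), and NOG, a BMP antagonist with 0 counts at E6.5, was at least 119-fold higher. HOX genes were 7 higher and 0 lower of 31, with HOXD11 at 1.53, HOXB9 at 1.33 and HOXA10 at 1.23. Hedgehog, FGF and Notch genes were 12 lower and 0 higher of 27, with FGF7 at -2.24, SPRY4 at -2.06 and ETV4 at -1.91. WNT genes included NOTUM, a secreted WNT inhibitor, at 3.01, and the WNT amplifiers LGR5 at -2.37 and RSPO1 at -2.32. Apoptosis genes were 2 higher and 4 lower of 26, with BMF at 1.80 and BCL2A1 at -2.19. The retinoic acid list had CRABP1 at -2.10, CRABP2 at -2.06 and ALDH1A3 at 1.98. Matrix genes were 3 higher and 8 lower of 38, led by MMP11 (-2.65), LAMA1 (-2.17) and LAMA2 (-1.94). Dissociation stress genes were 10 lower and 3 higher of 25, with KLF4 at -2.69. In the epithelium smooth muscle genes were 6 higher and 0 lower of 15 (median 0.78, percentile 100), with MYLK at 2.84. Epithelial junction and keratin genes were 6 higher and 0 lower of 23, with ITGB4 at 2.36 (0.66 to 4.72, from 3 counts at E6.5), KRT23 at 1.71 and CDH1, the epithelial cadherin, at 1.46. MSX2 (2.79) and MSX1 (at least 3.98-fold higher) in male epithelium were below their levels in erythroid-like cells, 43.7 CPM and 20.99 CPM.

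Of the genes named in advance, WNT7A, made by duct epithelium, was higher in male epithelium (1.41), and PAX2 (1.37) and WNT4 (1.01) were higher in male mesenchyme. Beside AMHR2 in mesenchyme, given above, the others reported here were between -0.51 (MMP2) and 0.48 (WNT4) in epithelium and between -0.79 (DMRT1) and 1.32 (LHX1) in mesenchyme. AMHR2 in epithelium had 4 and 0 counts. The share of male mesenchyme-like cells with an AMHR2 UMI was 1.45% (1.16 to 1.79) at a median of 5875 UMIs, and 0 of 304 erythroid-like cells had one at a median of 7222 UMIs, which allows up to 1.21%. After thinning, 0.412% of mesenchyme-like cells had one, with 51 too shallow. Male mesenchyme-like cells were mostly in cluster 2 (77.57%), which held 4557 male cells of 4574. Without male replicate 2 the lower count in the epithelium was 39, and with each channel clustered alone it was 61. Without E6.5 replicate 1 the counts were 49 higher and 83 lower in mesenchyme and 45 and 20 in epithelium. Genes on the Z chromosome had a median log2 ratio of 0.14 in mesenchyme and 0.30 in epithelium, beside -0.06 and -0.03 for autosomal genes. Here too stage, sex makeup and channel cannot be told apart.

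Male and female ducts were compared at E8.5, when sexual differentiation of the duct is under way. The largest differences were in mesenchyme-like cells. GATA5, a zinc-finger factor (ENSGALG00010022343, chromosome 20, 8362322 to 8373705), was at 98.92 CPM in the male and 0.0664 CPM in the female, a log2 ratio of 10.54 (8.69 to 13.59) that rests on 2 female counts. MSX1 was at 243.2 CPM against 0.199 CPM, a log2 ratio of 10.25 (9.13 to 11.70), and TBX20 (ENSGALG00010019019, chromosome 2, 47151932 to 47188712) was at 76.82 CPM against 0.166 CPM, a log2 ratio of 8.86 (7.63 to 10.48). PENK (6.71) and CLEC14A (6.15) were next among called autosomal genes with a symbol and at least 50 CPM in the higher group. Lower in the male were RASD1, a RAS-related protein (-5.31), OSR2 (-4.51), OSGIN1 (-3.80), BMP7, a secreted BMP ligand (-3.40), and FSTL4 (-3.28). In the epithelium TAGLN was at 339.9 CPM in the male and 14.04 CPM in the female, a log2 ratio of 4.60 (4.34 to 4.87), and erythroid-like cells of the male held 2.999 CPM. RBFOX1 (4.08), SH3BGR (3.81), AvBD10 (3.51) and ACTG2 (3.33) were higher in the male. DLX5 (-3.29), WIF1, a secreted WNT inhibitor (-3.22), ADARB2 (-3.05), MSX2 (-2.94) and UNC5D, a netrin receptor (-2.62), were lower.

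**Figure D4:**
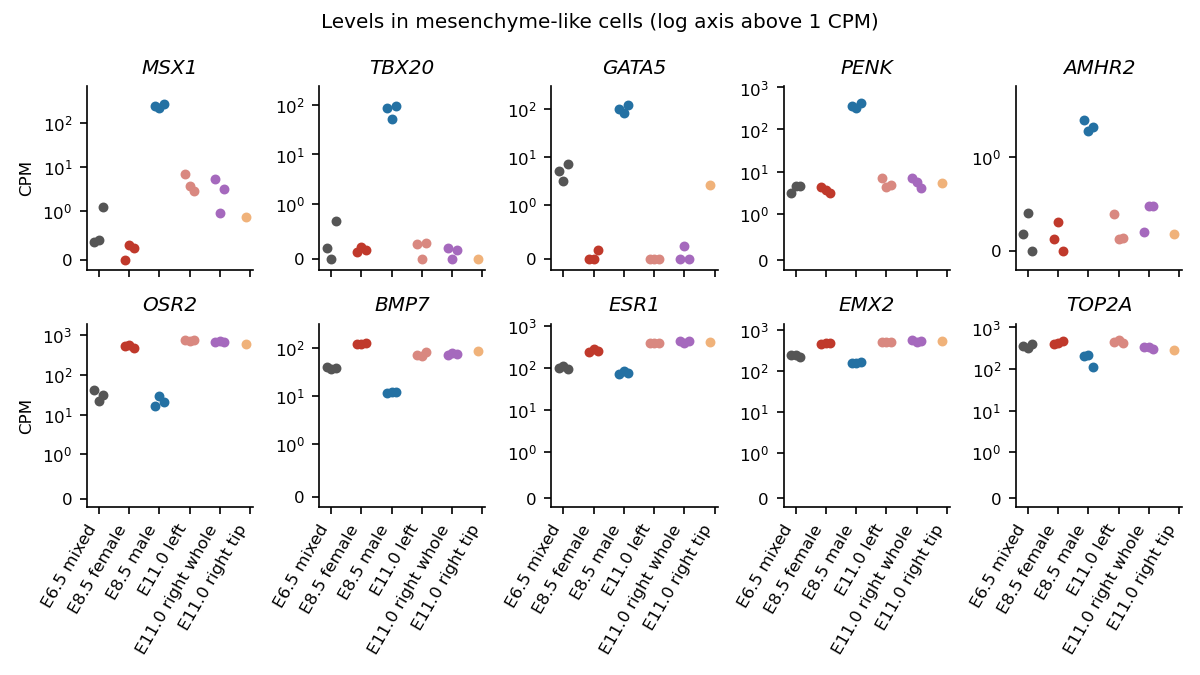
CPM of 10 genes in mesenchyme-like cells (y axis, logarithmic above 1 CPM and linear below) for each technical replicate of each group. MSX1 is at 243.2 CPM in the E8.5 male and 0.199 CPM in the E8.5 female, and OSR2 at 22.82 CPM and 520.3 CPM.

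Of the list genes, 63 were higher and 66 lower in the male of 375 measured in mesenchyme, and 40 were higher and 22 lower of 343 in epithelium. Cell cycle genes were again the list with the most lower members: 28 of 31 were lower in male mesenchyme and 0 higher, with a median of -1.37 (percentile 0.00), RRM2 at -3.10, GINS2 at -1.90 and MCM2, part of the replicative helicase, at -1.87. In epithelium their median was -0.58 (percentile 0.00) and 0 of 31 were called. The E8.5 female had 20.32% of its mesenchyme-like cells in the cycling cluster 5 and the male 1.99%, beside 4.51% in the cycling cluster 18 that held male cells alone. AMH and BMP genes were 8 higher and 1 lower of 27 in mesenchyme (median 0.39, percentile 99.86), with NOG at 7.89 (6.34 to 10.17, from 3 female counts) and AMHR2 at 4.15 (2.74 to 6.05). In epithelium they were 5 higher and 6 lower of 24, with MSX1 at -2.15 and ID1, a target of BMP signals, at -2.13. WNT genes were 10 higher and 4 lower of 35 in mesenchyme, with NOTUM at 3.53, WNT11 at 2.53 and APCDD1, a WNT antagonist, at -2.70, and SFRP5 (3.97) and RSPO3 (2.08) were higher in male epithelium. Hedgehog, FGF and Notch genes included the Notch ligand DLL1 (3.63), HEY2 (2.98) and FGFR3 (2.92) in mesenchyme and IHH (-1.83) and FGF9 (-1.80) in epithelium.

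HOX genes were 5 lower and 1 higher of 31 in male mesenchyme, with HOXD13 at -2.82, HOXA11 at -1.87 and HOXA13 at -1.54, and HOXD11 (-0.93) was not called. Duct formation factors held GATA3 at 4.03, PAX2 at 2.63 and SALL1 at -1.81, and GATA3 was at 4.863 CPM in male mesenchyme and 4.284 CPM in male erythroid-like cells. Steroid axis genes included ESR1 at -1.77, from 78.56 CPM against 267.3 CPM, STS, steroid sulfatase, at 2.00 and HSD17B4 at 1.19. Retinoic acid genes had a median of 0.57 (percentile 99.77), with RXRG at 1.54, CRABP1 at 1.80 and CRABP2 at -1.92. Apoptosis genes were 2 higher and 3 lower of 26, with BMF at 2.25 and BCL2A1 at -1.76. Matrix genes were 7 higher and 4 lower of 38, with the matrix proteases MMP9 at 3.30 and MMP16 at 2.10 and the proteoglycan BGN at -2.27. Mesenchymal transition genes included TGFB3 at 2.65, TGFBR2 at 1.98 and VIM at -1.89. Left-right and laterality genes were 1 higher and 2 lower of 7 (median 0.51, percentile 92.05), oviduct secretory products 3 higher and 0 lower of 6 (median 0.89, percentile 95.28), and hypoxia and glycolysis genes 1 higher and 2 lower of 18 (median -0.11, percentile 19.78). In the epithelium smooth muscle genes were 8 higher and 0 lower of 15 (median 1.21, percentile 100), with MYL9 at 2.25, and junction and keratin genes were 4 higher and 0 lower of 23, with ITGB4 at 2.44 and KRT7 at 1.56. The lower matrix genes LUM and DCN and the lower transition gene TWIST2 in male epithelium were below erythroid-like levels in the female.

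Of the genes named in advance, EMX2 was lower in male mesenchyme (-1.59), PGR, the progesterone receptor (1.01), was higher there, and WNT7A was higher in male epithelium (1.05). Beside AMHR2, PAX2 and ESR1, given above, the others reported here lay between -0.72 (DMRT1) and 0.51 (LHX1) in mesenchyme and between -0.23 (DMRT1) and 0.36 (MMP2) in epithelium. Genes on the Z chromosome, of which males carry a pair, had a median log2 ratio of 0.72 in epithelium (434 of 483 above 0) and 0.74 in mesenchyme (427 of 535 above 0), beside -0.02 and 0.01 for autosomal genes. Dissociation stress genes were 3 higher and 4 lower of 25 in mesenchyme, with KLF4 at -2.12 and NR4A3 at 1.70. Male cells were mostly in cluster 2, whose leading genes include MSX1, TBX20, GATA5, PENK and CLEC14A, and female cells in cluster 1, and sex and channel cannot be told apart. Without male replicate 2 the lower count in epithelium was 38. At a Leiden resolution of 0.3, where few female cells stayed in the class, the cell cycle median was 0.01, HOXA11 was at 0.57, HOXA13 at 2.59, WNT11 at -0.61, PGR at -0.13 and the lower count 39.

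The left female duct, which becomes the oviduct of birds, was compared between E11.0 and E8.5, where the female group is not split by side. In duct epithelium-like cells PCSK2, a prohormone convertase (ENSGALG00010017927, chromosome 3, 11682154 to 11779544), was at 96.2 CPM against 0.553 CPM, a log2 ratio of 7.44 (6.21 to 9.07). RORB (5.86), MGP, matrix Gla protein (5.04), EFEMP1 (4.15) and BMP3 (3.97) were higher too, and MGP had 0 counts in erythroid-like cells. ADARB2 (-4.54), SLC17A8, a vesicular glutamate transporter (-3.94), UNCX, a homeobox factor (-3.66), CXCR4, a chemokine receptor (-3.30), and APBB1IP (-3.28) were lower. In mesenchyme-like cells RAB3C (3.88), SRD5A2, a steroid reductase (2.97), AHRR (2.65), PRDM1 (2.56) and CDH13 (2.54) were higher, and DPP6 (-2.38), SORBS2 (-2.13), OPRM1, the mu opioid receptor (-2.07), AIF1L (-1.48) and NGFR (-1.43) were lower.

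In epithelium 58 list genes were higher and 14 lower of 349, and 23 of the 58 were at or below their levels in erythroid-like cells of the left duct. These include 10 of the 15 higher matrix genes and 7 of the 8 higher smooth muscle genes, such as ACTA2 (3.47) at 22.1 CPM against 82.51 CPM in erythroid-like cells, and LOX (2.17) at 17.43 CPM against 72.51 CPM. POSTN (3.42) was at 292.3 CPM against 200.0 CPM. COL1A2 was at 203.1 CPM in this epithelium and 882.7 CPM in the 69 erythroid-like cells, so the erythroid-like level can overstate free RNA. AMH and BMP genes were 10 higher and 1 lower of 24 (median 0.51, percentile 100), with BMP5 at 2.72, MSX2 at 2.07 and GATA2 at 2.82, and MSX2 stood at 364.3 CPM against 27.5 CPM in erythroid-like cells. SFRP5 (2.43), WNT11 (-2.01) and LEF1, a WNT effector (-1.89), were called among WNT genes, CDH2 (-1.82), KRT7 (1.53) and KRT18 (1.22) among junction and keratin genes, and DLL1 (-2.46) and HES5 (1.84) among Notch genes. In mesenchyme 29 were higher and 7 lower of 364. Smooth muscle genes there were 5 higher and 0 lower of 17 (median 0.74, percentile 100), with ACTG2 at 2.62, and TAGLN (2.07) and MYH11 (1.92) were at or below erythroid-like levels. FGF7 (3.70) and FGF9 (2.11), both growth factors, NOTUM (2.30), SFRP5 (1.96), LOX (1.78) and COL14A1 (1.35) were higher, and WIF1 (-1.75) was lower. HOX genes had a median of 0.24 (percentile 100) and 1 of 31 was higher.

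Of the genes named in advance, PGR was higher in E11.0 epithelium at 17.28 CPM against 2.321 CPM, a log2 ratio of 2.90 (2.21 to 3.64), and WNT4 was higher in mesenchyme (1.27). The others reported here were between -0.57 (LHX1) and 0.98 (WNT7A) in epithelium and between -0.93 (DMRT1) and 0.61 (ESR1) in mesenchyme. Of E11.0 duct epithelium-like cells, 39.4% were in cluster 13, led among others by MGP, which held 0.47% of those of the E8.5 female. E11.0 mesenchyme-like cells were in clusters 4 (33.68%), 7 (31.1%) and 5 (20.92%), and stage and channel cannot be told apart. At a Leiden resolution of 0.3, ACTG2 was at -0.17, CDH13 at -0.03, COL14A1 at -0.72, FGFR3 (1.70 in the main clustering) at -0.84 and SFRP5 at -1.66.

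The right female duct, which regresses in birds, was compared with the left at E11.0, as whole ducts. On the fixed lists 2 genes were higher on the right and 4 lower of 356 in mesenchyme, and 1 was higher and 2 lower of 344 in epithelium. In data simulated from E8.5 female mesenchyme the rule found 98.2% of 3-fold differences but 48.3% of 2-fold ones, which lie on its cutoff. Differences of up to about 2-fold can thus go uncalled in such data. The right duct replicates varied more. In epithelium the SD of log2 ratios between right whole replicates was 0.32 to 0.46, against 0.16 to 0.17 in E8.5 female mesenchyme. Larger differences can therefore go uncalled here, and these counts do not show that the ducts are alike. In mesenchyme KLF4 (ENSGALG00010014323, chromosome Z, 56393942 to 56398448) was at 15.35 CPM on the right and 58.87 CPM on the left, a log2 ratio of -1.94 (-2.14 to -1.74), and ATF3 was at -1.03 (-1.19 to -0.86). Both belong to the dissociation stress list, whose median was -0.22 (percentile 0.00). CRABP1 (-1.12) and CLDN3 (-1.73) were lower too, at or below erythroid-like levels on the left, and WNT11 (1.16) and PTGDS (1.35) were higher. In epithelium STS was higher (1.25), and the death receptor TNFRSF1A (-1.93) and BMP4 (-1.01) were lower, and these 7 genes beside KLF4 and ATF3 were picked for naming after their values were seen. Cell cycle genes had medians of -0.40 in mesenchyme and -0.34 in epithelium, both at percentile 0.00, with 0 of 31 called in either. In smooth muscle-like cells 0 list genes were higher and 10 lower of 339, and 8 of the 10 were cell cycle genes (median -0.82). ESR1 was at 438.7 CPM and 407.2 CPM in mesenchyme and 287.3 CPM and 268.2 CPM in epithelium, right and left. The other genes named in advance and reported here, with at least 20 counts in 1 group, were between -0.64 (PGR) and 0.44 (MMP2) in mesenchyme and between -0.24 (WNT7A) and 0.26 (PGR) in epithelium. Leaving out right replicate 2 gave 20 lower genes in epithelium and 10 in mesenchyme, and side and channel cannot be told apart.

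The tip of the right duct was compared with the right whole duct, both from 1 channel. In mesenchyme of the tip 11 of 29 HOX genes were lower and 2 higher. HOXD11 (ENSGALG00010024780, chromosome 7, 15930374 to 15936559) was at 0.353 CPM against 85.8 CPM, a log2 ratio of -7.92 (-10.97 to -6.07). HOXA11 (-7.47, -9.75 to -5.92), HOXA13 (-6.89, -9.94 to -5.03), HOXD10 (-6.32) and HOXA10 (-5.69) were lower as well. FGF7, HOXD11, HOXA11 and HOXA13 are among the leading genes of cluster 7, which held 33.45% of mesenchyme-like cells of the whole duct and 0.1% of those of the tip. A captured UMI of HOXD13 was seen in 0 of 997 tip cells (up to 0.369%) at a median of 5456 UMIs and in 6.87% of right whole duct cells at 5193 UMIs. After thinning the shares were 0% and 4.01%, with 27 and 83 cells too shallow, and cells with the RNA but no captured UMI are not counted. FGF7 (-3.89) and FGF10 (-1.90) were lower in the tip, and CNGA3 (2.19), COL8A1 (1.86), CYTL1 (1.54), HSPB9 (1.53), MYL4 (1.52) and HEY2 (2.12) were higher. In the epithelium of the tip WNT16 (3.47), ALDH1A1, an enzyme of retinoic acid synthesis (3.20), GATA6 (2.95), CNGA3 (2.82) and SOX17 (2.55) were higher. WNT16, from 65 and 20 counts, is also a leading gene of cluster 3, which is mesothelium-like, and doublets or misplaced cells were not ruled out as its source. MSX1 (-5.79, -11.10 to -3.29, from 1 tip count), HMP19 (-5.25, -8.30 to -3.38, from 2), GATA2 (-5.06), MSX2 (-4.95) and MGP (-4.64) were lower.

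In epithelium 25 list genes were higher and 34 lower of 313, and in mesenchyme 16 and 24 of 341. These counts depend on the processing. With a filter of 100 counts, 9 were higher and 17 lower in epithelium and 10 higher in mesenchyme. With no low-count filter, 48 and 28 were higher. The higher count in mesenchyme was 6 at a Leiden resolution of 0.3 and 8 with smooth muscle-like cells joined. AMH and BMP genes were 3 higher and 5 lower of 23 in epithelium (median -0.22, percentile 0.23). Retinoic acid genes had RXRA at -1.95 and CYP26B1, which degrades retinoic acid, at -1.72 beside ALDH1A1. Steroid axis genes were 3 higher and 1 lower of 19, with NR2F1 at 2.26, GREB1 at 2.07 and STS at -1.80, and ESR1 was at 596.7 CPM against 287.3 CPM, a log2 ratio of 1.05 (0.90 to 1.21). Duct formation factors held GATA3 at -2.14 (-5.25 to -0.16, from 2 tip counts) and WT1 at 1.80, and Notch genes HEY2 at -2.12 and JAG1 at 1.65. Matrix genes were 2 higher and 9 lower of 34, with 1 of the 2 and 4 of the 9 at or below their levels in erythroid-like cells, and POSTN (-3.09) was at 258.9 CPM in the whole duct against 218.9 CPM in its erythroid-like cells. In mesenchyme matrix genes were 4 higher and 0 lower of 37, with BGN at 1.30 and TNC at 1.23, and smooth muscle genes 4 higher and 0 lower of 16 (median 0.81), with ACTG2 at 1.56, MYH11 at 1.38 and ACTA2 at 1.06. Dissociation stress genes were 1 higher and 2 lower of 25 there, with a median of 0.47 (percentile 100).

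Of the genes named in advance, MMP2 (1.01) was higher and WNT4 (-1.46) lower in tip epithelium, and PGR was higher in tip mesenchyme (1.12). WNT4 in whole duct epithelium, 23.95 CPM, was below its erythroid-like level of 29.31 CPM. Beside ESR1 in epithelium, given above, the others reported here were between -1.04 (DMRT1) and 0.65 (PGR) in epithelium and between -0.34 (WNT4) and 0.55 (MMP2) in mesenchyme. The tip has 128 duct epithelium-like cells, none of them in cluster 13, which held 46.85% of those of the whole duct. Cluster 16, with SOX17 and ALDH1A1 among its leading genes, held 57.81% of those of the tip and 6.91% of those of the whole duct. Joined with smooth muscle-like cells, an alternative chosen after the data were seen, ACTG2 was at -1.45 and MYH11 at -0.70 in the tip, and at a Leiden resolution of 0.3 FGF7 was at 1.35. Leaving out right whole replicate 3 gave 9 higher genes in mesenchyme, and leaving out replicate 2 put the matrix median in epithelium at 0.08.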

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

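Of the tests of this part, that of the E8.5 male over E6.5 cells without W RNA was chosen only after the result was seen. In mesenchyme-like cells 6 genes lay on opposite sides of E6.5 in the female and male ducts at E8.5, in every technical replicate, with log2 ratios to E6.5 of at least 1 either way. BMP7, a BMP ligand, was at 1.69 in the female and -1.70 in the male. APCDD1, a WNT antagonist, was at 1.25 and -1.46, and JAG2, a Notch ligand, at 1.27 and -1.40. RRM2, a cell cycle gene, was at 1.01 and -2.09. PAX2 was at -1.26 in the female and 1.37 in the male, and GATA3 at -3.00 and 1.03, with GATA3 at or near its level in erythroid-like cells where it was higher. The difference between the sexes in these ratios was not tested, since each group is 1 channel.

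MSX1, TBX20, GATA5, PENK and CLEC14A stand out in mesenchyme-like cells of the E8.5 male, with log2 ratios to the female between 6.15 and 10.54. Free RNA in the male library was set against this: it would put the genes at a like level in erythroid-like cells, and the median log2 ratio of mesenchyme-like over erythroid-like male cells was 3.28 (SD 0.62 over the genes), which argues against it as the whole cause. Cells of a kind taken along in the male dissection alone stay open. In clusters under 90% male the median log2 ratio of male over female was 3.88, with single genes from -1.28 (CLEC14A) to 7.15 (GATA5). Male cells there held MSX1 at 2.99, TBX20 at 0.4725, GATA5 at 9.449 and CLEC14A at 0.315 CPM. Male erythroid-like cells held more, at 20.99, 9.425, 17.14 and 5.57 CPM, but less PENK (20.14 against 52.29 CPM). Of these cells, 841 of 1053 male ones were in cluster 6 and 5065 of 7069 female ones in cluster 1. The ratio therefore cannot tell such cells apart from a difference between the sexes. A difference between the sexes already there at E6.5 stays open too. Mesenchyme-like E6.5 cells without over with RNA of the 4 W genes had a median log2 ratio of 0.39 (SD 1.26), from few counts. That median leaves out TBX20, with 3 counts on each side, and with TBX20 it was -0.03. Single genes ran from -0.48 (GATA5) to 2.39 (CLEC14A), with PENK at -0.03 and MSX1 a bound from 7 and 0 counts. The E8.5 male over E6.5 cells without W RNA had a median of 6.61 (SD 1.20), so these E6.5 cells were below the E8.5 male. That ratio compares stages and does not measure a gap between the sexes. MSX1, TBX20, PENK and CLEC14A were also already known to lead the male ratios to E6.5. Sex itself may be the source, and channel and sex coincide.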

How the results depend on the processing

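The alternatives that join smooth muscle-like cells, remove the highest 5% of Scrublet scores, use 4 W genes and use HINTW alone were chosen after seeing the data. Over all alternatives, 7775 of 8136 named-gene values stayed the same within their spread, 338 moved and 23 reversed. For list medians these were 1303, 191 and 19 of 1513. Of counts of list genes 410 of 456 stayed within 1.5-fold. Of class shares 192 of 228 stayed within the SD over technical replicates or, for the single tip portion, within the counting interval. These totals hold values that could hardly move, so they do not measure robustness. Other minimum counts do not alter a gene's ratio, and all 427 named-gene values stayed the same under each. Leaving out a technical replicate was judged against a spread over those same replicates, for shares too. For named genes 2346 values stayed the same there and 13 moved. No value reversed with median of ratios size factors, with totals without haemoglobin, mitochondrial and ribosomal protein genes, or with the mean of log2 values. Unless stated, the cause was not tested.

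At a Leiden resolution of 0.3, 139 named genes moved and 16 reversed. Mesenchyme-like shares were 29.86% at E6.5, 4.72% in the E8.5 female, 20.42% in the left, 24.56% in the right whole duct and 32.69% in the tip. Smooth muscle-like shares were 11.32% at E6.5, 69.82% in the E8.5 female, 3.12% in the male, 57.47% in the left, 56.27% in the right whole duct and 46.40% in the tip. In mesenchyme, the E8.5 female against E6.5 had 12 higher and 29 lower, matrix median 0.14, left-right median -0.14, CDH1 0.21, EMX2 -0.36, HOXD11 -0.46, TBX18 0.48 and WNT6 -0.27. The male against E6.5 had a left-right median of 0.58. The left duct against the E8.5 female had 16 lower, matrix median -0.21, ACTG2 -0.17, CDH13 -0.03, COL14A1 -0.72, FGFR3 -0.84 and SFRP5 -1.66. Male against female had 39 lower, cell cycle median 0.01, mesenchymal transition median -0.30, DES -0.78, HOXA11 0.57, HOXA13 2.59, PGR -0.13 and WNT11 -0.61. Right against left had 2 lower, and the tip against the whole duct 6 higher and FGF7 at 1.35.

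At a resolution of 1.0, mesenchyme-like shares were 49.67% in the left duct and 44.31% in the tip. Smooth muscle-like shares were 2.57% in the E8.5 female, 0.22% in the male, 27.63% on the left and 34.54% in the tip, and the mesothelium-like share of the male 14.85%.

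With each channel clustered alone, 97 named genes moved and 2 reversed. The E8.5 female against E6.5 had 47 lower in epithelium with HOXA10 at -0.93 and HOXA9 at -0.39, and in mesenchyme a matrix median of 0.19 and a stress median of 0.08. The male against E6.5 had 61 lower in epithelium, and in mesenchyme a matrix median of 0.37 and a left-right median of 0.32. Right against left had 2 higher and 4 lower in epithelium. At E6.5 the shares were 10.16% epithelium-like, 31.27% mesenchyme-like, 17.30% smooth muscle-like and 15.02% mesothelium-like. Mesenchyme-like shares were 74.92% in the E8.5 female and 33.36% in the tip. Smooth muscle-like shares were 0% in the E8.5 female and 0% in the male, 31.61% on the left and 45.65% in the tip.

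With the highest 5% of Scrublet scores removed, the E8.5 female against E6.5 had 10 higher and 24 lower in epithelium and COL6A1 at -0.94. The left-right median of male against E6.5 mesenchyme was 0.22, and TWIST2 of male against female epithelium 0.03. Right against left epithelium had 10 lower. Tip epithelium had 21 lower, a matrix median of 0.38 and OGN at 1.16. The epithelium-like share of the left duct was 7.42%. With smooth muscle-like cells joined to mesenchyme-like cells, right against left had 1 higher and 2 lower, and the tip 8 higher, ACTG2 at -1.45 and MYH11 at -0.70.

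With a filter of 100 counts fewer genes were tested. The E8.5 female against E6.5 epithelium had 10 higher, and the left duct against the E8.5 female mesenchyme 4 lower. Right against left had 0 higher and 0 lower in epithelium and 0 higher and 2 lower in mesenchyme. The tip had 9 higher and 17 lower in epithelium and 10 higher in mesenchyme. With no low-count filter, the left-right median of male against E6.5 mesenchyme was 0.02, right against left epithelium had 4 lower, and the tip had 48 higher in epithelium and 28 in mesenchyme.

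Without a cell filter, right against left epithelium had 2 higher and 4 lower. At E6.5 the shares were 3.93% epithelium-like, 30.56% mesenchyme-like and 18.32% mesothelium-like, on the left 28.91% smooth muscle-like, and in the tip 37.26% mesenchyme-like and 37.26% smooth muscle-like. With the stricter cell filter, the E6.5 epithelium-like share was 6.49% and the left-right median of male against E6.5 mesenchyme 0.17. With the deeper group thinned, that median was 0.23 and right against left epithelium had 6 lower. With the mean of log2 values over technical replicates, right against left mesenchyme had 2 lower.

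Leaving out 1 technical replicate at a time gave these ranges. Male against E6.5 epithelium had 18 to 39 lower and male against female epithelium 21 to 38, the highest both without E8.5 male replicate 2. Right against left had 1 to 3 higher and 1 to 20 lower in epithelium, and 1 to 4 higher and 3 to 10 lower in mesenchyme; the highest lower counts came without right whole replicate 2. The tip had 9 to 21 higher in mesenchyme, 9 without right whole replicate 3. The smooth muscle median of the E8.5 female against E6.5 mesenchyme ran from -0.01, without E6.5 replicate 1, to 0.26. The left-right median of male against E6.5 mesenchyme ran from -1.17, without E8.5 male replicate 2, to 0.24, without E6.5 replicate 1, and was 0.17 without E6.5 replicate 2. The matrix median of tip epithelium ran from -0.21 to 0.08, the latter without right whole replicate 2.

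Depth limits the W shares, given as E6.5, E8.5 female, E8.5 male, left, right whole and tip. Thinned to 2000 UMIs they were 33.50%, 56.93%, 10.26%, 56.57%, 60.29% and 58.51%. With at least 2 UMIs they were 49.62%, 47.84%, 7.58%, 43.90%, 64.21% and 61.52%. With 4 W genes they were 40.76%, 72.65%, 0.02%, 69.70%, 83.53% and 81.96%, and with HINTW alone 36.92%, 59.85%, 0.02%, 57.47%, 72.25% and 67.39%. Depth also limits epithelium-like cells of the tip, which number 128, and AMHR2, with 4 counts in E8.5 female mesenchyme.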

Other observations

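Of the tests of this part, the deeper cells and cell class tests of W RNA at E6.5 were chosen only after that result was seen, and so were the genes and lists named in this paragraph, which were not recomputed under the alternatives. Smooth muscle-like cells of the left duct at E11.0 had 54 list genes higher and 8 lower of 338 measured than the 786 in the E8.5 female, with MYLK at 2.63, ACTA2 at 2.42 and CALD1 at 1.63. The cells differ in cluster: 99.87% of the E8.5 female ones were in cluster 0, and 24.07% of the left ones in cluster 9, which MYH11, ACTG2 and TAGLN lead. On the right at E11.0 these cells had 0 list genes higher and 10 lower of 339 than on the left, 8 of them cell cycle genes such as PLK1 (-1.31), RRM2 (-1.25) and CDK1 (-1.05), with a list median of -0.82 (percentile 0.00). In the right tip, smooth muscle-like cells had 12 of 30 HOX genes lower and mesothelium-like cells 13 of 28, with HOXA9 at -2.86 and -2.46, and cluster 9 held 0.3% of the smooth muscle-like cells of the tip and 24.34% of those of the right whole duct. Mesothelium-like cells of the E8.5 male had 7 of 22 dissociation stress genes lower than the female, ATF3 (-2.48) the most.

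E6.5 replicate 1 had more W-chromosome RNA than replicates 2 and 3. Cells of replicate 1 were not deeper, with a median of 10146 UMIs against 10657 and 10186 in replicates 2 and 3, which argues against depth. The thinned share with RNA of the 4 W genes was still 3.15-fold that of the higher of the others. Since replicate 1 was not deeper, this thinned share adds no further support. Another mix of cell classes is argued against by HINTW within mesenchyme-like cells alone, at 1.36 for replicate 1 over replicate 3. More female cells in replicate 1 would lower its Z genes, and for replicate 1 over replicate 3 their median less that of autosomal genes was -0.38 or lower in mesothelium-like and Wolffian duct-like cells, which is consistent with a higher female share and so with separate pools of embryos under the tags. Over replicate 2 the Z medians were -0.37 and -0.30, beside autosomal medians of 0.05 and 0.04.

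Among 1857 E6.5 cells with at least 10000 UMIs, 1053 had no W RNA and 726 had at least 2 UMIs of it. Z genes were higher in the E8.5 male than in the E8.5 female, by a median of 0.74 in mesenchyme-like cells. A difference between 10x channels would be absent within 1 channel, yet mesenchyme-like E6.5 cells without W RNA had a median for Z genes less that for autosomal genes of 0.68 over cells with it, which argues against channel. Sex chromosome dose may therefore lie behind the median, though not behind each gene: DMRT1, a Z gene, was at 0.56 (0.42 to 0.69) in these E6.5 cells and at -0.72 (-0.78 to -0.66) in mesenchyme-like cells of the E8.5 male over the female. Mesenchyme-like E6.5 cells without and with W RNA were also compared within replicates 1 and 3. Of 295 fixed-list genes measured in both, 0 were at least 2-fold apart the same way. Cells without and with W RNA numbered 68 and 168 in replicate 1 and 240 and 106 in replicate 3. Differences under 2-fold are not covered by this count.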
